A study of Arabidopsis thaliana with 24 samples.

How the data were processed

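RNA from whole roots of Arabidopsis seedlings, moved to standard medium or to medium with 140 mM NaCl for 1, 3 or 20 hours or 2, 4 or 8 days, was measured on 24 1-colour Agilent arrays, 2 per group. Per the labels, total RNA was extracted with RNeasy columns and labelled with Cy3 by the Quick Amp method. The deposited scanner files hold spot intensities that, per the file headers, the authors obtained with Feature Extraction 10.1.1.1, and their processed signal was background-subtracted and detrended but not normalized between arrays. The deposited log2 values of the series differed from the log2 of the same processed signal by a constant for each array (highest SD of the difference 5.8e-07) and covered 31641 of the 43603 probes. How that constant and those probes were chosen is not given in the sources used here.

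The intensities of the scanner files were used. Each array had 43803 non-control spots, 68.6% to 85.5% of them well above background, and 0 saturated spots. Spots called non-uniform by the scanner software (954, or 0.0907%) were left out, and 255 spots called population outliers were kept. The processed signal was taken to log2 and each array's 75th percentile was subtracted. Probes were kept if well above background on both arrays of at least 1 group, which left 34159. Each gene was represented by its probe of highest mean over all arrays, giving 25952 genes, of which 22709 carried a locus and 3243 another target name, and 6344 had more than 1 kept probe. Probes were joined to genes by locus name alone, because probe sequences were not used here and the header's annotation is older than the gene table. Copies of near-identical genes, such as those of LHCB1 and RBCS, KIN1 and KIN2, the CBF genes, or PIP2;2 and PIP2;3, were therefore not told apart.

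A linear model with 12 group means was fitted in limma 3.58.1 under R 4.3.3 (data.table, version 1.17.8) with empirical Bayes moderation. Contrasts were salt against standard medium at each time, their mean, the differences between consecutive times, and each later time against 1 hour in standard medium. Moderated F tests covered the response at any time and the differences between times. Adjusted p is the Benjamini-Hochberg value within a contrast, with a threshold of 0.05. The fit had 12 residual and 1.9 prior degrees of freedom, a median residual SD of 0.214 and a median standard error of 0.21, so that a change of 0.452 on the log2 scale reached an unadjusted p of 0.05 for a gene of median error. A gene dim on both arrays of 1 medium is given as at least a fold, computed against the level at which spots were called above background.

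Gene lists were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over 204 tests (34 lists, 6 times), and again with the correlation estimated per list. The lists held 571 memberships, of which 552 were measured, and 2 members were dropped because the gene table gave their locus other names. Where a list lost its call without more than 1 single array, the highest adjusted p is given. Members were also counted with p-values adjusted over the list alone. Lists, tests, alternatives and the rule for naming genes were chosen before the data were examined, except where a later choice is named.

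Named genes were, per time, the 8 with the highest and the 8 with the lowest log2 fold among genes past the threshold with the same sign in both replicate pairs and above background on all 4 arrays. Added to these were the 3 with the highest bound in each direction among genes dim in 1 medium, up to 4 members of each described list with the smallest adjusted p, any member past the threshold against its list, and 10 key genes at every time. For the mean, the steps and the standard course the 5 highest and 5 lowest were eligible. For length, not all 658 eligible results are printed. Beside the key genes, those printed were picked for a known role after the values were seen. Many of the largest folds, of genes without a described role, are left out. For the lists called at no time, members were taken at 3 hours, which was also decided after the data were seen.

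The fit was tested on simulated data with 25620 genes and no change but 50 genes at each of 4 sizes. At 1 hour it recovered 10%, 52%, 82% and 96% of changes of 0.5, 1, 2 and 4 on the log2 scale with 5.51% false calls, and at 8 days 10%, 50%, 86% and 92% with 6.3%. The F test of differences between times recovered 0%, 16%, 68% and 72%, and 0%, 14%, 72% and 78%. A list shifted down was found in all 4 list tests (adjusted p from 5.16e-23 to 1.72e-05), and camera called 1 other list, at 1 hour with the preset correlation. How often lists of correlated genes are called falsely stays open.

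Alternatives were normexp background correction (offset 50), quantile or median scaling, no filter or only probes above background on all arrays, the mean of a gene's probes, the deposited log2 values, a trended robust variance, the replicate number or the slide as a block, only the 4 arrays compared, each array left out, a 2-fold minimum and a threshold of 0.01. Normexp was planned with the mean spot signal and was run with the median spot signal and local background. Counts with the slide as a fixed block stand beside each salt count.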

Results

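Arabidopsis seedlings grown for 5 days were moved to standard medium or to medium with 140 mM NaCl. Whole roots were collected 1, 3 and 20 hours and 2, 4 and 8 days later. The 12 groups had 2 arrays each, spread over 6 slides of 4 arrays, and each slide held 1 replicate of both media at 2 consecutive times. The median signal of the arrays ranged from 225 to 464 and the 75th percentile from 1537 to 2627. After filtering, 25952 genes were tested with limma. The labels gave the age at the last time as 11 days, while 5 days of growth and 8 days of treatment add up to 13. Values in brackets after a gene are the log2 fold of salt over standard medium with the standard error of the fit, 2 arrays per medium. A list's counts are given over all genes and again adjusted over the list alone. The p-values measure only the spread between these samples, because the labels do not say whether the replicates were separate cultures. Salt arrays always lay at slide positions 1 or 3 and standard arrays at 2 or 4, so that medium and position could not be told apart.

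The first question was which genes responded to salt at all and on average over the times. Averaged over the 6 times, LEA7, which codes for a protein protecting dried cells, rose most (6.81 ± 0.35, adjusted p = 2.31e-09), and ADH1 for alcohol dehydrogenase rose as well (5.38 ± 0.13, adjusted p = 8.76e-12). The abscisic acid (ABA) receptor gene PYL6 fell (-3.93 ± 0.32, adjusted p = 2.05e-07). Of the 27 genes of the ABA response list 26 rose and 0 fell (26 and 1 over the list alone), with a median log2 fold of 1.95 (camera adjusted p = 1.76e-18, 0.0552 with estimated correlation). In the cell cycle list 31 of 34 genes fell and 1 rose (32 and 1 over the list alone). The median was -0.58 (adjusted p = 3.07e-10, 0.292 with estimated correlation). Among the dehydrins and LEA genes 14 of 15 rose and 0 fell (14 and 0 over the list alone). The dehydrins and LEA median was 2.62 (adjusted p = 2.9e-08, 0.0561 with estimated correlation). The moderated F test over the 6 times called 14045 genes, and the mean salt effect called 13387, 5744 higher and 7643 lower. With slides as a fixed block these were 16392 and 15086 genes.

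**Figure D1:**
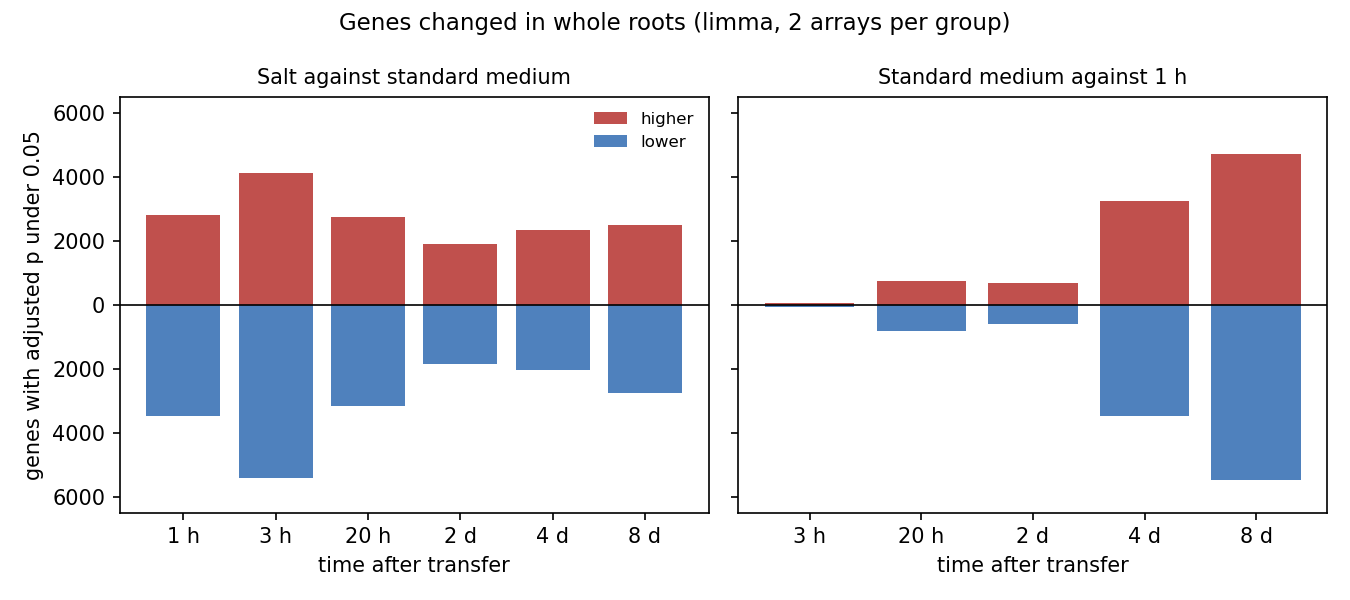
Genes with adjusted p under 0.05 in limma, 2 arrays per group, for salt against standard medium at each time and for standard medium against 1 hour. At 3 hours 4119 genes were higher and 5432 lower in salt, the largest counts of the 6 times.

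At 1 hour the question was which genes responded first. NCED3, the gene of the rate-limiting step of ABA synthesis, rose 220-fold (7.78 ± 0.39, adjusted p = 1.13e-08), and CYP707A3, which codes for an enzyme breaking ABA down, fell (-4.55 ± 0.56, adjusted p = 3.54e-05). DREB2A, a regulator of drought and heat responses, rose (4.67 ± 0.34, adjusted p = 3.28e-07), as did GOLS2 of raffinose synthesis (7.19 ± 0.46, adjusted p = 9.31e-08). Of the ABA response list 24 of 27 genes rose and 1 fell (24 and 1 over the list alone), among them ABI2 (3.65 ± 0.16, adjusted p = 5.91e-09), with a median of 2.94 (camera adjusted p = 1.75e-22, 0.0888 with estimated correlation). HAI2, another phosphatase gene of the ABA pathway, was dim in standard medium and rose at least 86.7-fold. RD29B, a marker of the ABA response, rose (5.79 ± 0.80, adjusted p = 9.83e-05), and RD29A rose too (2.30 ± 0.63, adjusted p = 0.0151), though the latter call ended without standard replicate 1 (adjusted p = 0.0973), salt replicate 1 (adjusted p = 0.067) or salt replicate 2 (0.0658). The dehydrins and LEA list had 13 of 15 genes higher and 0 lower (13 and 0 over the list alone), for example EM6 (5.69 ± 0.47, adjusted p = 8.98e-07). The dehydrins and LEA median was 4.69 (adjusted p = 5.21e-10, 0.0888 with estimated correlation). Early stress transcription factors rose in 20 of 31 cases and fell in 3 (20 and 4 over the list alone), with ATAF1 higher (3.00 ± 0.14, adjusted p = 7.08e-09) and RAV1 lower (-1.55 ± 0.24, adjusted p = 0.000225). The list median was 1.91 (adjusted p = 1.85e-11, 0.0888 with estimated correlation).

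In the nitrogen list at 1 hour 6 of 11 genes fell and 0 rose (6 and 0 over the list alone), among them the ammonium transporter gene AMT1;3 (-2.44 ± 0.24, adjusted p = 4.08e-06) and the nitrate transporter gene NRT2.1 (-4.60 ± 0.75, adjusted p = 0.000398), which was well above background on 1 of 2 salt arrays. The median was -1.58 (adjusted p = 0.00137, 0.303 with estimated correlation). The cytokinin list had 10 of 17 genes lower and 1 higher (11 and 1 over the list alone), with the synthesis gene IPT3 lower (-4.41 ± 0.46, adjusted p = 7.99e-06, above background on 1 of 2 salt arrays). The cytokinin median was -0.91 (adjusted p = 0.00233, 0.18 with estimated correlation). Root hair genes fell in 7 of 26 cases and rose in 0 (7 and 0 over the list alone), for example COBL9 (-1.32 ± 0.28, adjusted p = 0.00288). The root hair median was -0.84 (adjusted p = 0.0019, 0.686 with estimated correlation). Iron deficiency genes fell in 6 of 15 cases and rose in 0 (9 and 0 over the list alone), with the regulator FRU lower (-2.00 ± 0.24, adjusted p = 2.61e-05). The iron deficiency median was -1.84, or -1.56 with dim members at their bound (adjusted p = 0.00341, 0.303 with estimated correlation). The compatible solutes list had 6 of 12 genes higher and 1 lower (7 and 2 over the list alone), and P5CS1 of proline synthesis rose (2.18 ± 0.30, adjusted p = 9.73e-05). The median was 0.86 (adjusted p = 0.000399, 0.0888 with estimated correlation). The circadian clock list had 9 of 18 genes higher and 2 lower (10 and 2 over the list alone), for example PRR5 (1.59 ± 0.18, adjusted p = 1.84e-05). The circadian clock median was 0.75 (adjusted p = 0.000531, 0.0942 with estimated correlation).

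Further list calls at 1 hour depended on single arrays. ABA receptor genes fell in 6 of 9 cases and rose in 2 (6 and 2 over the list alone), with PYL4 lower (-4.13 ± 0.32, adjusted p = 5.37e-07) and PYL7 higher (4.89 ± 0.34, adjusted p = 1.92e-07). The ABA receptor median was -1.46 (adjusted p = 0.0293, 0.303 with estimated correlation, 0.0691 without standard replicate 1). Heat shock (2 of 16 higher, 0 lower, the same over the list alone; median 0.46, or 0.28 with dim members at their bound; adjusted p = 0.0251, 0.485 with estimated correlation) lost its call without standard replicate 2 (adjusted p = 0.0693), although HSFA6B, a heat stress regulator, rose (7.78 ± 0.65, adjusted p = 9.91e-07). Jasmonate genes rose in 8 of 20 cases and fell in 1 (8 and 2 over the list alone). The jasmonate median was 0.34 (adjusted p = 0.0418, 0.485 with estimated correlation, 0.136 without salt replicate 2). Expansins and XTH, genes of wall loosening, fell in 8 of 26 cases and rose in 3 (9 and 3 over the list alone), with XTH16 lower (-4.66 ± 0.32, adjusted p = 2.09e-07). The median was -0.59 (adjusted p = 0.0421, 0.276 with estimated correlation, 0.0799 without standard replicate 1). Green tissue had 1 of 30 genes higher (0 over the list alone). The green tissue median was 0.23 (adjusted p = 0.0453, 0.828 with estimated correlation, 0.147 without salt replicate 2). In limma 6260 genes passed at 1 hour, 2787 higher and 3473 lower, and 7661 with slides as a fixed block. Of these, 192 genes called higher were dim in standard medium.

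**Figure D2:**
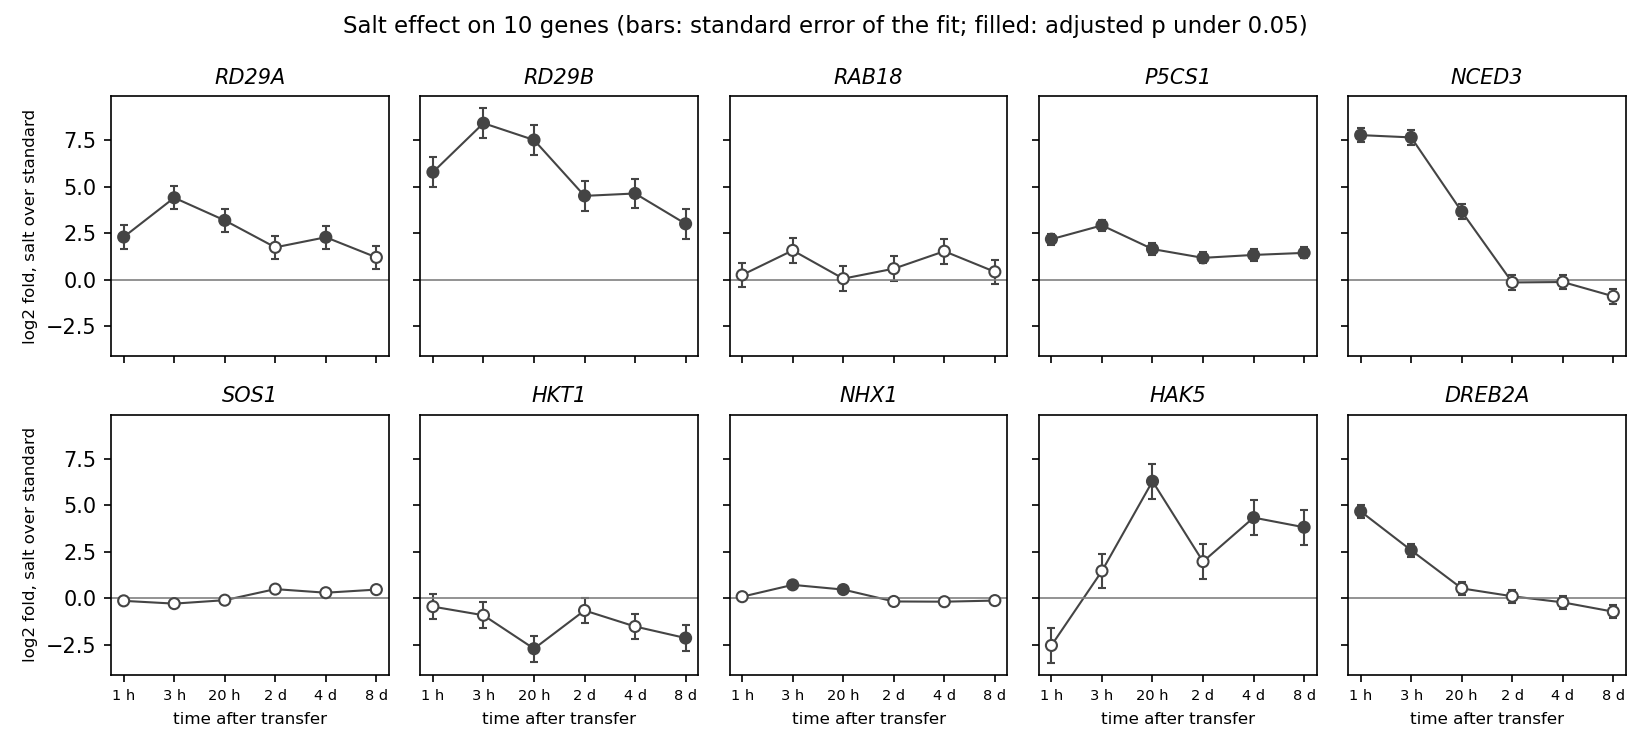
Log2 fold of salt over standard medium for 10 genes chosen before the data were examined, with the standard error of the limma fit. NCED3 stood at 7.78 at 1 hour and HAK5 at 6.29 at 20 hours.

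At 3 hours the question was how far the early response had spread. NCED3 was still 202-fold higher (7.66 ± 0.39, adjusted p = 1.06e-08), RD29A (4.41 ± 0.63, adjusted p = 7.72e-05) and RD29B (8.42 ± 0.80, adjusted p = 2.14e-06) had their highest folds of the 6 times, and COR15B, a protectant of chloroplast membranes, rose at least 640-fold. Of the ABA response list 25 of 27 genes rose and 0 fell (26 and 0 over the list alone). The ABA response median was 3.23 (camera adjusted p = 1.98e-21, 0.0888 with estimated correlation). Of the 9 ABA receptor genes 7 fell and 1 rose (7 and 1 over the list alone), PYL6 most (-6.08 ± 0.79, adjusted p = 3.4e-05). The ABA receptor median was -1.35 (adjusted p = 0.00364, 0.216 with estimated correlation). Cell cycle genes fell in 31 of 34 cases and rose in 0 (32 and 0 over the list alone), among them the cyclin genes CYCA1;1 (-1.74 ± 0.13, adjusted p = 2.78e-07) and CYCB1;3 (-1.81 ± 0.17, adjusted p = 1.87e-06). The median was -1.18 (adjusted p = 8.4e-12, 0.276 with estimated correlation). Suberin genes, which build the barrier around the endodermis, rose in 12 of 14 cases and fell in 0 (13 and 0 over the list alone), with the regulator MYB41 (5.57 ± 0.40, adjusted p = 1.66e-07) and GPAT7 (4.97 ± 0.41, adjusted p = 5.91e-07) as examples. The suberin median was 2.1 (adjusted p = 3.82e-08, 0.276 with estimated correlation). Heat shock genes rose in 12 of 16 cases and fell in 0 (12 and 0 over the list alone), HSP70 among them (2.00 ± 0.29, adjusted p = 8.94e-05). The heat shock median was 1.57, or 1.73 with dim members at their bound (adjusted p = 1.85e-05, 0.216 with estimated correlation).

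The dehydrins and LEA list had 13 of 15 genes higher at 3 hours and 0 lower (14 and 0 over the list alone), for example LEA4-5 (9.22 ± 0.66, adjusted p = 1.78e-07). The dehydrins and LEA median was 3.41, or 3.25 with dim members at their bound (adjusted p = 4.97e-11, 0.0888 with estimated correlation). Early stress transcription factors rose in 20 of 31 cases and fell in 4 (21 and 4 over the list alone), with NAC019 at least 227-fold higher and RAV1 lower (-2.20 ± 0.24, adjusted p = 6.45e-06). The median was 1.25 (adjusted p = 2.02e-07, 0.0888 with estimated correlation). Compatible solute genes rose in 6 of 12 cases and fell in 2 (7 and 2 over the list alone), with the sucrose synthase gene SUS1 higher (5.23 ± 0.27, adjusted p = 1.24e-08) and ERD5, of proline breakdown, lower (-2.20 ± 0.22, adjusted p = 3.4e-06). The compatible solute median was 1.69 (adjusted p = 0.00279, 0.142 with estimated correlation). Flavonoid genes rose in 6 of 8 cases and fell in 0 (7 and 0 over the list alone), F3H for example (1.40 ± 0.28, adjusted p = 0.00122). The flavonoid median was 1.09, or 0.98 with dim members at their bound (adjusted p = 0.00718, 0.44 with estimated correlation). Cytokinin genes fell in 11 of 17 cases and rose in 3 (11 and 3 over the list alone). The cytokinin median was -0.98 (adjusted p = 0.0173, 0.238 with estimated correlation). Iron deficiency genes fell in 8 of 15 cases and rose in 1 (9 and 1 over the list alone), among them the ferric reductase gene FRO2 (-2.96 ± 0.40, adjusted p = 4.73e-05). The median was -1.60, or -1.35 with dim members at their bound (adjusted p = 0.0207, 0.43 with estimated correlation). NHX1, a vacuolar sodium exchanger gene, rose (0.72 ± 0.14, adjusted p = 0.000902).

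Aquaporin genes fell in 8 of 19 cases at 3 hours and rose in 0 (8 and 0 over the list alone), PIP2;4 for example (-2.36 ± 0.37, adjusted p = 0.000186), but the list call ended without standard replicate 1 (adjusted p = 0.234) or salt replicate 2 (0.103). The aquaporin median was -0.44, or -0.49 with dim members at their bound (adjusted p = 0.0421, 0.713 with estimated correlation). The circadian clock list (6 of 18 higher, 2 lower, the same over the list alone; median 0.44, adjusted p = 0.044, 0.301 with estimated correlation) lost its call without standard replicate 1 (adjusted p = 0.0558), standard replicate 2 (adjusted p = 0.0509) or salt replicate 2 (0.062), although CCA1 rose (2.92 ± 0.38, adjusted p = 3.63e-05). The xylem and secondary wall list passed with 0 of 13 genes called (limma, 0 over the list alone; median 0.50, camera adjusted p = 0.0486, 0.758 with estimated correlation) and not without salt replicate 2 (adjusted p = 0.256). At 3 hours 9551 genes passed, 4119 higher and 5432 lower, and 11247 with slides as a fixed block.

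At 20 hours the question was what remained after the first day. HAK5, a potassium uptake gene, rose 78.3-fold (6.29 ± 0.93, adjusted p = 0.000288), and HKT1, which retrieves sodium from the xylem, fell (-2.71 ± 0.69, adjusted p = 0.0113), a call that ended without standard replicate 1 (adjusted p = 0.0742) or salt replicate 2 (0.134). All 14 suberin genes rose (14 and 0 over the list alone), among them FAR1 (4.32 ± 0.38, adjusted p = 4.24e-06) and FAR4 (3.19 ± 0.26, adjusted p = 2.44e-06). The suberin median was 2.37 (camera adjusted p = 4.25e-14, 0.183 with estimated correlation). Heat shock genes rose in 13 of 16 cases and fell in 0 (14 and 0 over the list alone), with HSP22.0 at least 454-fold higher. The heat shock median was 2.42 (adjusted p = 1.49e-11, 0.0888 with estimated correlation). Root hair genes, lower at 1 hour, rose in 11 of 26 cases and fell in 0 (18 and 0 over the list alone), RHD2 among them (0.90 ± 0.18, adjusted p = 0.00289). The median was 1.31 (adjusted p = 7.61e-07, 0.485 with estimated correlation).

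Of the ABA response list 20 of 27 genes were higher at 20 hours and 0 lower (21 and 1 over the list alone), HAI3 for example (6.14 ± 0.48, adjusted p = 1.59e-06). The ABA response median was 2.14 (adjusted p = 5.76e-17, 0.0888 with estimated correlation). RD29B was 184-fold higher (7.52 ± 0.80, adjusted p = 2.09e-05), well above background on 1 of 2 standard arrays. NCED3 had come down to 12.7-fold (3.67 ± 0.39, adjusted p = 2e-05). Of the dehydrins and LEA genes 8 of 15 rose and 0 fell (10 and 0 over the list alone), LEA7 most (10.24 ± 0.85, adjusted p = 2.55e-06). The median was 1.42, or 1.55 with dim members at their bound (adjusted p = 3.02e-06, 0.183 with estimated correlation). Phenylpropanoid genes rose in 5 of 11 cases and fell in 0 (9 and 1 over the list alone), with CAD5 of lignin synthesis higher (1.37 ± 0.16, adjusted p = 4.53e-05). The phenylpropanoid median was 0.80 (adjusted p = 0.000138, 0.226 with estimated correlation). Indole glucosinolate and camalexin genes rose in 8 of 14 cases and fell in 0 (8 and 0 over the list alone), with the regulator MYB34 higher (1.81 ± 0.17, adjusted p = 7.54e-06). The median was 0.75, or 0.80 with dim members at their bound (adjusted p = 0.000611, 0.417 with estimated correlation). Hypoxia genes rose in 4 of 10 cases and fell in 0 (4 and 1 over the list alone), ADH1 above all (5.78 ± 0.33, adjusted p = 1.32e-07). The hypoxia median was 0.70 (adjusted p = 0.00976, 0.407 with estimated correlation). Expansins and XTH rose in 10 of 26 cases and fell in 4 (12 and 5 over the list alone), with EXPA10 higher (4.61 ± 0.23, adjusted p = 5.69e-08) and XTH15 lower (-2.09 ± 0.25, adjusted p = 4.88e-05). The expansins and XTH median was 0.73 (adjusted p = 0.0188, 0.216 with estimated correlation).

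Early stress transcription factors rose in 10 of 31 cases at 20 hours and fell in 3 (12 and 3 over the list alone), with ERF2 higher (3.03 ± 0.38, adjusted p = 6.98e-05). The list median was 0.80 (adjusted p = 0.00019, 0.183 with estimated correlation). Compatible solute genes rose in 6 of 12 cases and fell in 2 (6 and 2 over the list alone), with GOLS2 higher (4.50 ± 0.46, adjusted p = 1.4e-05). The median was 1.00 (adjusted p = 0.023, 0.216 with estimated correlation). Aquaporin genes fell in 8 of 19 cases and rose in 0 (10 and 0 over the list alone), TIP2;2 for example (-1.12 ± 0.21, adjusted p = 0.00176). The aquaporin median was -0.66 (adjusted p = 0.00288, 0.544 with estimated correlation). ABA receptor genes fell in 7 of 9 cases and rose in 0 (7 and 1 over the list alone), PYL5 among them (-1.90 ± 0.30, adjusted p = 0.000491). The ABA receptor median was -0.80 (adjusted p = 0.00347, 0.216 with estimated correlation). Iron deficiency genes fell in 7 of 15 cases and rose in 0 (8 and 0 over the list alone), with FRO2 lower (-3.96 ± 0.40, adjusted p = 1.35e-05). The iron deficiency median was -0.79, or -0.69 with dim members at their bound (adjusted p = 0.00416, 0.303 with estimated correlation).

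Without standard replicate 2 at 20 hours the calls of 3 lists ended. These were jasmonate (4 of 20 higher, 0 lower, the same over the list alone; median 0.39, adjusted p = 0.0249, 0.44 with estimated correlation, 0.0607 without it), cytokinin (5 of 17 lower, 2 higher, 6 and 2 over the list alone; median -0.49, adjusted p = 0.0304, 0.276 with estimated correlation, 0.0742 without it and 0.0539 without salt replicate 2) and cell cycle (limma called 0 of 34, 0 over the list alone; median -0.25, camera adjusted p = 0.0261, 0.761 with estimated correlation, 0.0803 without it and 0.149 without salt replicate 1). In all 5916 genes passed at 20 hours, 2748 higher and 3168 lower, and 7508 with slides as a fixed block. The count was 3494 without standard replicate 1, 3322 without standard replicate 2, 3569 without salt replicate 1 and 3726 without salt replicate 2.

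**Figure D3:**
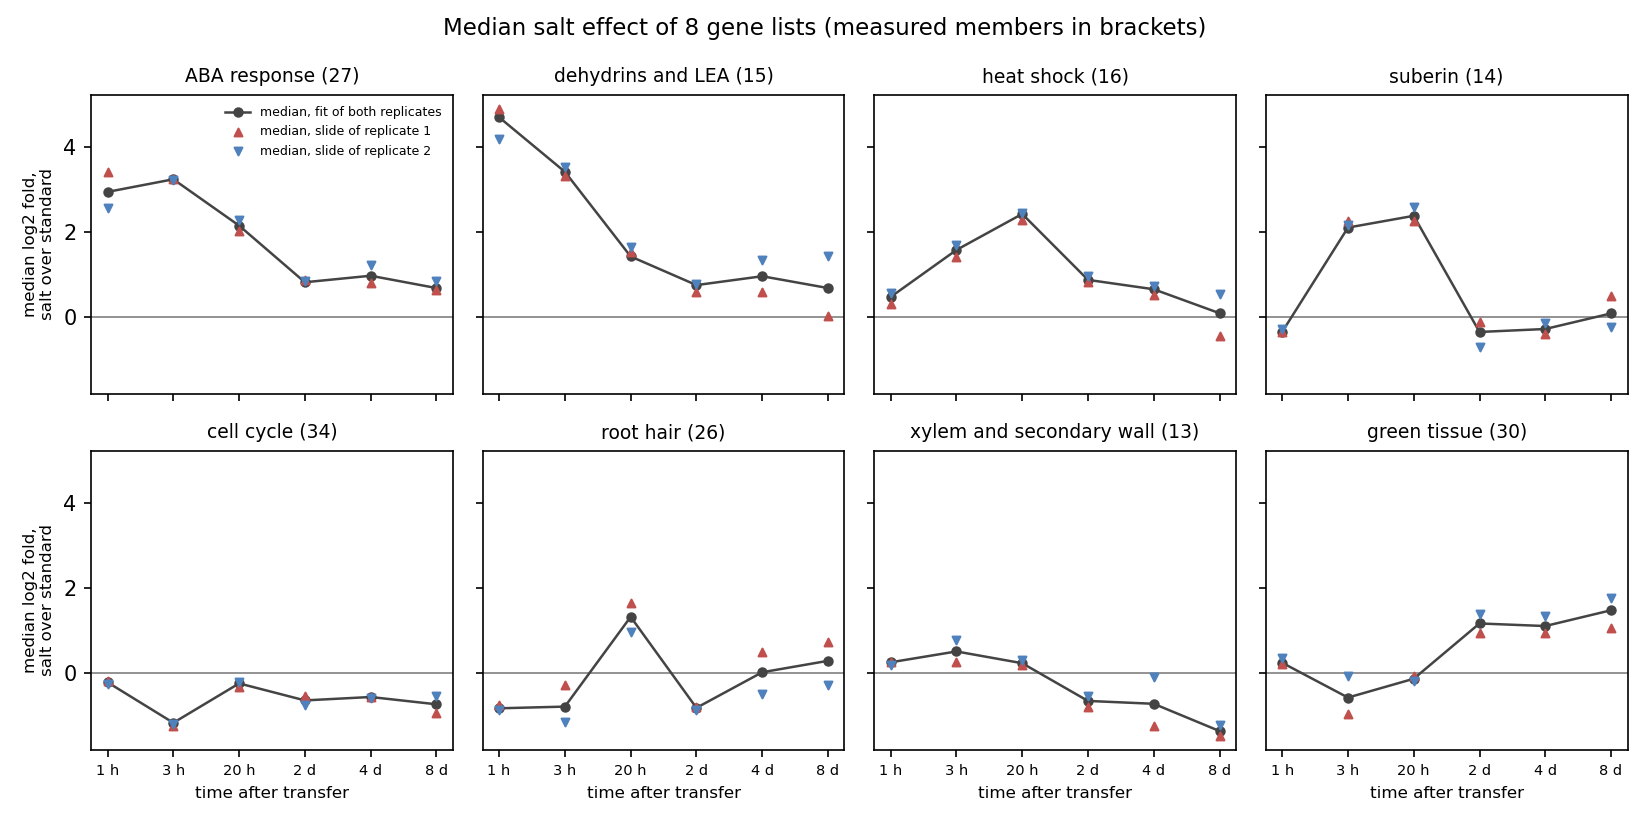
Median log2 fold of salt over standard medium for 8 gene lists, from the fit of both replicates and from each replicate's slide alone. The root hair median was -0.84 at 1 hour and 1.31 at 20 hours.

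At 2 days the question was which changes outlasted the first day. BGLU18, a glucosidase gene that releases ABA from its sugar conjugate, rose 61.6-fold (5.94 ± 0.34, adjusted p = 7.98e-07), and NRT1.5, which loads nitrate into the xylem, fell 32.8-fold (-5.04 ± 0.55, adjusted p = 9.49e-05). Genes of green tissue rose in 22 of 30 cases and fell in 0 (28 and 0 over the list alone), among them the light-harvesting genes LHCB2.2 (2.16 ± 0.34, adjusted p = 0.000984) and LHCB5 (1.28 ± 0.24, adjusted p = 0.00325). The median was 1.16 (camera adjusted p = 7.11e-14, 0.303 with estimated correlation). Cell cycle genes fell in 19 of 34 cases and rose in 0 (27 and 1 over the list alone), with the mitotic kinase gene AUR1 lower (-1.0 ± 0.18, adjusted p = 0.00241). The cell cycle median was -0.66 (adjusted p = 8.94e-11, 0.303 with estimated correlation). Of the ABA response list 13 of 27 genes rose and 0 fell (17 and 0 over the list alone), with RD29B still 22.8-fold higher (4.51 ± 0.80, adjusted p = 0.0023) while NCED3 no longer passed (-0.14 ± 0.39, adjusted p = 0.868). The ABA response median was 0.81 (adjusted p = 1.09e-08, 0.216 with estimated correlation).

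Hypoxia genes rose in 5 of 10 cases at 2 days and fell in 0 (6 and 0 over the list alone), PCO1 for example (2.63 ± 0.32, adjusted p = 0.000202). The hypoxia median was 1.2 (adjusted p = 6.89e-06, 0.183 with estimated correlation). Jasmonate genes rose in 4 of 20 cases and fell in 0 (10 and 0 over the list alone), with the storage protein gene VSP2 higher (3.54 ± 0.51, adjusted p = 0.000629). The median was 0.79, or 0.68 with dim members at their bound (adjusted p = 2.29e-05, 0.193 with estimated correlation). Heat shock genes rose in 5 of 16 cases and fell in 0 (8 and 0 over the list alone), HSP22.0 at least 6.29-fold. The heat shock median was 0.87, or 0.74 with dim members at their bound (adjusted p = 9.9e-05, 0.263 with estimated correlation). Indole glucosinolate and camalexin genes rose in 5 of 14 cases and fell in 0 (7 and 0 over the list alone), with MYB34 higher (1.42 ± 0.17, adjusted p = 0.000194). The list median was 0.65, or 0.70 with dim members at their bound (adjusted p = 0.000138, 0.343 with estimated correlation). Aquaporin genes fell in 6 of 19 cases and rose in 0 (8 and 0 over the list alone), TIP2;2 among them (-1.74 ± 0.21, adjusted p = 0.000209). The aquaporin median was -0.47 (adjusted p = 0.000611, 0.485 with estimated correlation). Compatible solute genes rose in 5 of 12 cases and fell in 0 (8 and 1 over the list alone), with SUS1 higher (2.50 ± 0.27, adjusted p = 9.44e-05). The median was 0.68 (adjusted p = 0.000638, 0.0888 with estimated correlation). Early stress transcription factors rose in 8 of 31 cases and fell in 1 (9 and 1 over the list alone), with ERF2 higher (3.68 ± 0.38, adjusted p = 5.91e-05). The early stress factor median was 0.37, or 0.27 with dim members at their bound (adjusted p = 0.00122, 0.216 with estimated correlation). Dehydrins and LEA genes rose in 3 of 15 cases and fell in 0 (6 and 0 over the list alone), LEA4-1 at least 2.1-fold. The median was 0.74, or 0.78 with dim members at their bound (adjusted p = 0.0173, 0.435 with estimated correlation).

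Some lists at 2 days moved with few or no single genes passing. Genes of the ribosome and nucleolus fell in 3 of 20 cases and rose in 0 (6 and 0 over the list alone). The list median was -0.45 (adjusted p = 6.69e-05, 0.543 with estimated correlation). The xylem and secondary wall list was lower with 0 of 13 genes called by limma (0 over the list alone). The median was -0.67 (camera adjusted p = 0.00358, 0.571 with estimated correlation). Root hair (3 of 26 lower, 0 higher, the same over the list alone; median -0.83, adjusted p = 0.0057, 0.758 with estimated correlation) lost its call without standard replicate 2 (adjusted p = 0.45) or salt replicate 1 (0.433). Cytokinin (3 of 17 lower, 0 higher, 4 and 0 over the list alone; median -0.50, adjusted p = 0.0251, 0.273 with estimated correlation) lost its call without standard replicate 1 (adjusted p = 0.0712), as did iron deficiency (7 of 15 lower, 0 higher, 7 and 1 over the list alone; median -0.82, or -1.12 with dim members at their bound; adjusted p = 0.0293, 0.44 with estimated correlation, 0.169 without it). Redox (5 of 17 higher, 1 lower, 7 and 1 over the list alone; median 0.22, adjusted p = 0.0421, 0.435 with estimated correlation, 0.17 without salt replicate 1) held the catalase gene CAT3 (2.06 ± 0.34, adjusted p = 0.00137). Phenylpropanoid genes rose in 2 of 11 cases (2 over the list alone; median 0.28, adjusted p = 0.0432, 0.501 with estimated correlation, 0.28 without salt replicate 1). In total 3759 genes passed at 2 days, 1902 higher and 1857 lower, 5509 with slides as a fixed block and 5771 with slides as a random block. The count was 2300 without standard replicate 1, 1310 without standard replicate 2, 2187 without salt replicate 1 and 1649 without salt replicate 2.

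At 4 days the question was whether the later state was settled. BGLU18 rose 135-fold (7.08 ± 0.34, adjusted p = 1.62e-07), NRT1.8, which removes nitrate from the xylem, rose 46.4-fold (5.54 ± 0.34, adjusted p = 8.8e-07), and NRT1.5 stayed lower (-4.33 ± 0.55, adjusted p = 0.000205). HAK5, dim in standard medium, rose by at least 4.34 on the log2 scale, a call that ended without salt replicate 1 (adjusted p = 0.0656). Green tissue genes rose in 21 of 30 cases and fell in 0 (27 and 0 over the list alone), LHCB2.2 for example (2.38 ± 0.34, adjusted p = 0.000415). The green tissue median was 1.09 (camera adjusted p = 5.35e-13, 0.303 with estimated correlation). Of the ABA response list 14 of 27 genes rose and 0 fell (15 and 0 over the list alone), with RD29B 25.0-fold higher (4.64 ± 0.80, adjusted p = 0.00157). The ABA response median was 0.96 (adjusted p = 1.07e-07, 0.261 with estimated correlation). Cell cycle genes fell in 12 of 34 cases and rose in 1 (26 and 2 over the list alone). The cell cycle median was -0.57 (adjusted p = 1.22e-07, 0.421 with estimated correlation).

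Jasmonate genes rose in 6 of 20 cases at 4 days and fell in 0 (8 and 0 over the list alone), with VSP1 higher (3.41 ± 0.51, adjusted p = 0.000642). The median was 0.68, or 0.60 with dim members at their bound (adjusted p = 2.13e-05, 0.193 with estimated correlation). Aquaporin genes fell in 7 of 19 cases and rose in 1 (9 and 1 over the list alone), with TIP2;3 lower (-3.07 ± 0.49, adjusted p = 0.000876) and PIP2;5 at least 3.17-fold higher. The aquaporin median was -0.46 (adjusted p = 0.000316, 0.462 with estimated correlation). Compatible solute genes rose in 5 of 12 cases and fell in 0 (5 and 0 over the list alone), SUS3 for example (2.01 ± 0.27, adjusted p = 0.000297). The compatible solute median was 0.44 (adjusted p = 0.000611, 0.0888 with estimated correlation). Indole glucosinolate and camalexin genes rose in 7 of 14 cases and fell in 0 (8 and 0 over the list alone). The list median was 0.69, or 0.72 with dim members at their bound (adjusted p = 0.00188, 0.44 with estimated correlation). Hypoxia genes rose in 2 of 10 cases and fell in 0 (3 and 0 over the list alone), with ADH1 higher (4.67 ± 0.33, adjusted p = 2.24e-06). The median was 0.56 (adjusted p = 0.003, 0.303 with estimated correlation). Phenylpropanoid genes rose in 4 of 11 cases and fell in 0 (5 and 0 over the list alone), with FAH1 higher (2.72 ± 0.46, adjusted p = 0.00141). The phenylpropanoid median was 0.38 (adjusted p = 0.00731, 0.404 with estimated correlation). Auxin genes fell in 5 of 22 cases and rose in 1 (5 and 2 over the list alone), among them LBD18 of lateral root formation (-2.12 ± 0.28, adjusted p = 0.000233, above background on 1 of 2 salt arrays) and the transporter gene PIN7 (-1.12 ± 0.18, adjusted p = 0.000826). The auxin median was -0.32 (adjusted p = 0.023, 0.18 with estimated correlation).

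ABA receptor genes fell in 4 of 9 cases at 4 days and rose in 0 (6 and 0 over the list alone), with PYL2 lower (-1.58 ± 0.32, adjusted p = 0.00422). The ABA receptor median was -0.54 (adjusted p = 0.0052, 0.216 with estimated correlation). Dehydrins and LEA genes rose in 5 of 15 cases and fell in 0 (7 and 0 over the list alone), with LEA7 higher (5.30 ± 0.85, adjusted p = 0.000955). The median was 0.95, or 0.92 with dim members at their bound (adjusted p = 0.00396, 0.343 with estimated correlation). Early stress transcription factors rose in 7 of 31 cases and fell in 2 (7 and 2 over the list alone), with MYB44 higher (0.99 ± 0.15, adjusted p = 0.000745). The list median was 0.38, or 0.49 with dim members at their bound (adjusted p = 0.00541, 0.276 with estimated correlation). Expansins and XTH rose in 5 of 26 cases and fell in 4 (9 and 4 over the list alone), with EXPA10 higher (4.13 ± 0.23, adjusted p = 2.55e-07) and XTH16 lower (-3.57 ± 0.32, adjusted p = 2.03e-05). The expansins and XTH median was 0.59 (adjusted p = 0.0194, 0.216 with estimated correlation). Ribosome and nucleolus genes fell in 1 of 20 cases (0 over the list alone). The list median was -0.35 (adjusted p = 0.00386, 0.674 with estimated correlation). The xylem and secondary wall list (3 of 13 lower, 0 higher, the same over the list alone; median -0.73, adjusted p = 0.00365, 0.571 with estimated correlation) lost its call without salt replicate 1 (adjusted p = 0.187) or standard replicate 1 (0.0683). Casparian strip genes (5 of 8 lower, 0 higher, the same over the list alone; median -0.84, adjusted p = 0.00976, 0.544 with estimated correlation) and heat shock genes (4 of 16 higher, 0 lower, 5 and 0 over the list alone; median 0.64, or 0.49 with dim members at their bound; adjusted p = 0.0151, 0.462 with estimated correlation) lost theirs without salt replicate 2 (adjusted p = 0.0919 and 0.0552). In limma 4375 genes passed at 4 days, 2322 higher and 2053 lower, and 5884 with slides as a fixed block. The count was 2808 without standard replicate 1, 1979 without standard replicate 2, 2104 without salt replicate 1 and 1951 without salt replicate 2.

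At 8 days the question was what the longest exposure changed. NRT1.8 (4.75 ± 0.34, adjusted p = 3.26e-06) and ADH1 (4.55 ± 0.33, adjusted p = 3.26e-06) stayed higher and NRT1.5 stayed lower (-4.90 ± 0.55, adjusted p = 6.39e-05). HAK5, dim in standard medium, was at least 7.83-fold higher, a call that ended without standard replicate 1 (adjusted p = 0.0565) or salt replicate 1 (0.0936), and HKT1 was lower (-2.14 ± 0.69, adjusted p = 0.0412), a call that ended without standard replicate 1 (adjusted p = 0.181), standard replicate 2 (adjusted p = 0.076) or salt replicate 1 (0.23). Green tissue genes rose in 24 of 30 cases and fell in 0 (24 and 0 over the list alone), among them PSAK of photosystem I (1.72 ± 0.20, adjusted p = 6.77e-05) and RCA, the activase of Rubisco (1.8 ± 0.24, adjusted p = 0.000241). The median was 1.47 (camera adjusted p = 3.41e-15, 0.276 with estimated correlation). Genes of the xylem and secondary wall fell in 11 of 13 cases and rose in 0 (12 and 0 over the list alone), with the cellulose synthase genes CESA7 (-1.49 ± 0.26, adjusted p = 0.00128) and CESA8 (-1.71 ± 0.32, adjusted p = 0.00226) as examples. The list median was -1.38 (adjusted p = 2.57e-06, 0.379 with estimated correlation). Cell cycle genes fell in 26 of 34 cases and rose in 1 (29 and 1 over the list alone), with PCNA2 of DNA replication lower (-0.96 ± 0.14, adjusted p = 0.000328). The cell cycle median was -0.75 (adjusted p = 1.37e-10, 0.303 with estimated correlation).

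The other list calls at 8 days each ended without at least 1 array. Of the ABA response list 10 of 27 genes rose and 0 fell (14 and 1 over the list alone), with KIN2 higher (1.77 ± 0.29, adjusted p = 0.00083). The ABA response median was 0.67, or 0.61 with dim members at their bound (adjusted p = 0.000315, 0.43 with estimated correlation, 0.133 without salt replicate 2). RD29B rose 8.06-fold (3.01 ± 0.80, adjusted p = 0.0163), a call that ended without standard replicate 1 (adjusted p = 0.0515), standard replicate 2 (adjusted p = 0.0807) or salt replicate 2 (0.145). Aquaporin genes fell in 6 of 19 cases and rose in 1 (6 and 1 over the list alone), with TIP2;2 lower (-1.61 ± 0.21, adjusted p = 0.000203). The median was -0.34 (adjusted p = 0.00629, 0.579 with estimated correlation, 0.33 without standard replicate 2). Phenylpropanoid genes rose in 3 of 11 cases and fell in 0 (5 and 0 over the list alone). The phenylpropanoid median was 0.47 (adjusted p = 0.0137, 0.43 with estimated correlation, 0.225 without salt replicate 1). Compatible solute genes rose in 4 of 12 cases and fell in 0 (6 and 0 over the list alone), with P5CS1 higher (1.45 ± 0.30, adjusted p = 0.00411). The compatible solute median was 0.40 (adjusted p = 0.0171, 0.216 with estimated correlation, 0.0812 without standard replicate 1). Ribosome and nucleolus genes fell in 1 of 20 cases (0 over the list alone). The ribosome and nucleolus median was -0.28 (adjusted p = 0.0205, 0.758 with estimated correlation, 0.243 without standard replicate 1). Iron deficiency genes fell in 4 of 15 cases and rose in 1 (4 and 1 over the list alone), with BHLH038 lower (-4.12 ± 0.78, adjusted p = 0.00219, above background on 1 of 2 salt arrays). The median was -1.08, or -1.02 with dim members at their bound (adjusted p = 0.0378, 0.462 with estimated correlation, 0.254 without salt replicate 1). Auxin genes fell in 6 of 22 cases and rose in 1 (6 and 1 over the list alone), with IAA19 lower (-1.38 ± 0.17, adjusted p = 0.000136). The auxin median was -0.27 (adjusted p = 0.0385, 0.193 with estimated correlation, 0.0684 without standard replicate 2). Early stress transcription factors rose in 8 of 31 cases and fell in 2 (8 and 2 over the list alone). The early stress factor median was 0.28, or 0.18 with dim members at their bound (adjusted p = 0.0455, 0.435 with estimated correlation, 0.172 without standard replicate 2). In all 5269 genes passed at 8 days, 2491 higher and 2778 lower, and 6819 with slides as a fixed block. The folds of the 2 slides had a correlation of 0.59.

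The 10 genes fixed beforehand also gave the following values. RAB18 passed at no time, with 0.26, 1.58, 0.0612, 0.60, 1.54 and 0.43 from 1 hour to 8 days (± 0.66, adjusted p = 0.846, 0.0776, 0.969, 0.625, 0.136 and 0.725). SOS1, the sodium exporter gene, passed at no time either, with -0.14, -0.29, -0.11, 0.49, 0.30 and 0.46 (± 0.16, adjusted p = 0.617, 0.186, 0.724, 0.0581, 0.246 and 0.0582). HKT1 did not pass at 1 and 3 hours or 2 and 4 days, with -0.45, -0.92, -0.66 and -1.52 (± 0.69, adjusted p = 0.721, 0.336, 0.6 and 0.156). NHX1 was higher at 20 hours (0.47 ± 0.14, adjusted p = 0.0253, 0.199 without salt replicate 1), and stood at 0.0835, -0.17, -0.19 and -0.13 at 1 hour and 2, 4 and 8 days (adjusted p = 0.747, 0.459, 0.416 and 0.592). HAK5 did not pass at 1 hour, 3 hours or 2 days, with -2.54, 1.47 and 1.97 (± 0.93, adjusted p = 0.0641, 0.248 and 0.183). DREB2A was higher at 3 hours (2.58 ± 0.34, adjusted p = 3.95e-05) and then stood at 0.53, 0.11, -0.22 and -0.72 (adjusted p = 0.312, 0.892, 0.743 and 0.16). NCED3 stood at -0.12 and -0.89 at 4 and 8 days (± 0.39, adjusted p = 0.897 and 0.128). P5CS1 was higher at 3 hours, 20 hours, 2 days and 4 days, with 2.93, 1.65, 1.18 and 1.34 (± 0.30, adjusted p = 4.41e-06, 0.00136, 0.0182 and 0.00816), the last 2 calls ending without single arrays (highest adjusted p 0.109 and 0.0727). RD29A was higher at 20 hours and 4 days, with 3.20 and 2.29 (± 0.63, adjusted p = 0.00236 and 0.0231, the latter 0.171 without salt replicate 2), and did not pass at 2 and 8 days, with 1.75 and 1.21 (adjusted p = 0.08 and 0.208).

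The next question was how the salt effect changed between times. From 1 to 3 hours the salt effect on LAC12, a laccase gene, rose (6.78 ± 0.77, adjusted p = 0.000123), as did that on CYP86A4 of cutin synthesis (5.97 ± 0.45, adjusted p = 1.45e-05), and the effect on BT1 fell (-4.96 ± 0.44, adjusted p = 2.61e-05). From 3 to 20 hours the effect on the root hair gene XTH12 rose (5.99 ± 1.06, adjusted p = 0.00281) and that on DIP2 fell (-4.81 ± 0.46, adjusted p = 6.71e-05). From 20 hours to 2 days BGLU44 moved up (4.30 ± 0.59, adjusted p = 0.00175) and the seed protein gene EM6 moved down (-5.21 ± 0.66, adjusted p = 0.00115). From 4 to 8 days AT3G63380, a calcium pump gene, fell (-2.79 ± 0.31, adjusted p = 0.0096), as did AT1G58320 (-2.78 ± 0.35, adjusted p = 0.0212). Both calls ended without salt replicate 2 of 4 days (adjusted p = 0.067 for AT3G63380 and 0.137 for AT1G58320) and with the replicate block (adjusted p = 0.0519 for both). The counts were 3775 genes from 1 to 3 hours (1915 up, 1860 down), 3040 from 3 to 20 hours (1638 up, 1402 down), 1167 from 20 hours to 2 days (552 up, 615 down), 0 from 2 to 4 days (limma, 497 genes at unadjusted p under 0.05) and 3 from 4 to 8 days (0 up, 3 down). With slides as a fixed block they were 5014, 4578, 2218, 2 and 4. The share of increases from 3 to 20 hours, 53.9%, was 38.6% when array medians were shifted to a common level and 39.8% in the deposited values.

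Single arrays moved these counts. From 1 to 3 hours 2513 genes passed without standard replicate 1 of 3 hours. From 3 to 20 hours 1582 passed without standard replicate 2 and 1640 without salt replicate 2 of 3 hours, 1576 without standard replicate 1 and 1799 without salt replicate 2 of 20 hours. From 20 hours to 2 days 563 and 372 passed without standard replicates 1 and 2 of 20 hours, 488 and 546 without salt replicates 1 and 2 of 20 hours, 663 and 435 without standard replicates 1 and 2 of 2 days, 447 without salt replicate 2 of 2 days, and 2006 without salt replicate 1 or 2 of 8 days. From 2 to 4 days 1 gene passed without standard replicate 2 of 2 days and 3 without salt replicate 1 of 4 days. From 4 to 8 days 431 passed without salt replicate 2 and 89 without standard replicate 2 of 8 days, 5 without standard replicate 1 of 8 days, 8 without salt replicate 1 and 0 without salt replicate 2 of 4 days, and 1 without each single array of 2 days. Effects at 2 and 4 days had a correlation of 0.81 across genes. Of 2743 genes called at both (634 for independent calls) 2742 had the same direction. Recovery by steps was not simulated, so few step calls do not show a settled effect. Between 1 hour and 20 hours the correlation was 0.28. At all 6 times 569 genes passed, 285 of them always higher and 218 always lower.

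The last question was how roots in standard medium alone changed after transfer. From 20 hours on the arrays lay on other slides than those of 1 hour, so that time and slide could not be told apart. By 8 days the root hair list had 22 of 26 genes lower and 1 higher than at 1 hour (23 and 1 over the list alone), for example RHD2 (-1.37 ± 0.18, adjusted p = 0.000126) and CSLD3 (-0.97 ± 0.12, adjusted p = 5.95e-05). The root hair median was -2.26 (camera adjusted p = 3.18e-07, 0.684 with estimated correlation). Expansins and XTH fell in 17 of 26 cases by 8 days and rose in 0 (19 and 0 over the list alone; median -1.26, adjusted p = 2.03e-05), and this list passed with estimated correlation as well (adjusted p = 0.0485), with EXPA10 lower (-1.74 ± 0.23, adjusted p = 0.000119). It had also passed at 20 hours (4 of 26 lower, 8 over the list alone; median -0.62, adjusted p = 3.52e-05), 2 days (3 of 26 lower, 8 over the list alone; median -0.70, adjusted p = 1.02e-05) and 4 days (15 of 26 lower, 20 over the list alone; median -1.12, adjusted p = 2.52e-06), each with adjusted p = 0.0485 with estimated correlation. Cell cycle genes fell in 26 of 34 cases by 8 days and rose in 0 (28 and 0 over the list alone), CYCA1;1 among them (-1.07 ± 0.13, adjusted p = 7.45e-05). The median was -0.78 (adjusted p = 4.93e-08, 0.615 with estimated correlation). Suberin genes fell at 20 hours in 11 of 14 cases and rose in 0 (12 and 0 over the list alone), with the transporter gene ABCG20 lower (-2.00 ± 0.29, adjusted p = 0.00265). The suberin median was -1.42 (adjusted p = 4.27e-11, 0.435 with estimated correlation). All 8 Casparian strip genes fell by 8 days (8 and 0 over the list alone), and CYP707A3, of ABA breakdown, was lower at 3 hours (-3.06 ± 0.56, adjusted p = 0.0278, a call that ended without any 1 of the 4 arrays, highest adjusted p 0.223) and at 20 hours (-4.29 ± 0.56, adjusted p = 0.0018). The Casparian strip median was -1.06 (adjusted p = 0.0047, 0.684 with estimated correlation).

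Against 1 hour 122 genes differed at 3 hours in standard medium (41 higher, 81 lower), 1564 at 20 hours (723 higher, 841 lower), 1269 at 2 days (673 higher, 596 lower), 6721 at 4 days (3247 higher, 3474 lower) and 10168 at 8 days (4700 higher, 5468 lower). At 3 hours the count was 254 with slides as a fixed block and 414 with slides as a random block, which gave 1535, 1150, 6816 and 10285 at the later times. The share of increases at 20 hours, 46.2%, was 32.7% after background correction without the spots of bright local background. Without standard replicate 2 of 1 hour the counts were 37, 296, 174, 2093 and 5326. At 3 hours 24 and 44 genes passed without standard replicates 1 and 2 of 3 hours, and 234 without salt replicate 1 or 2 of 8 days. Without standard replicates 1 and 2 of the later time the counts were 427 and 179 at 20 hours, 215 and 282 at 2 days and 2908 and 4022 at 4 days, and at 8 days 6774 passed without standard replicate 2.

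**Figure D4:**
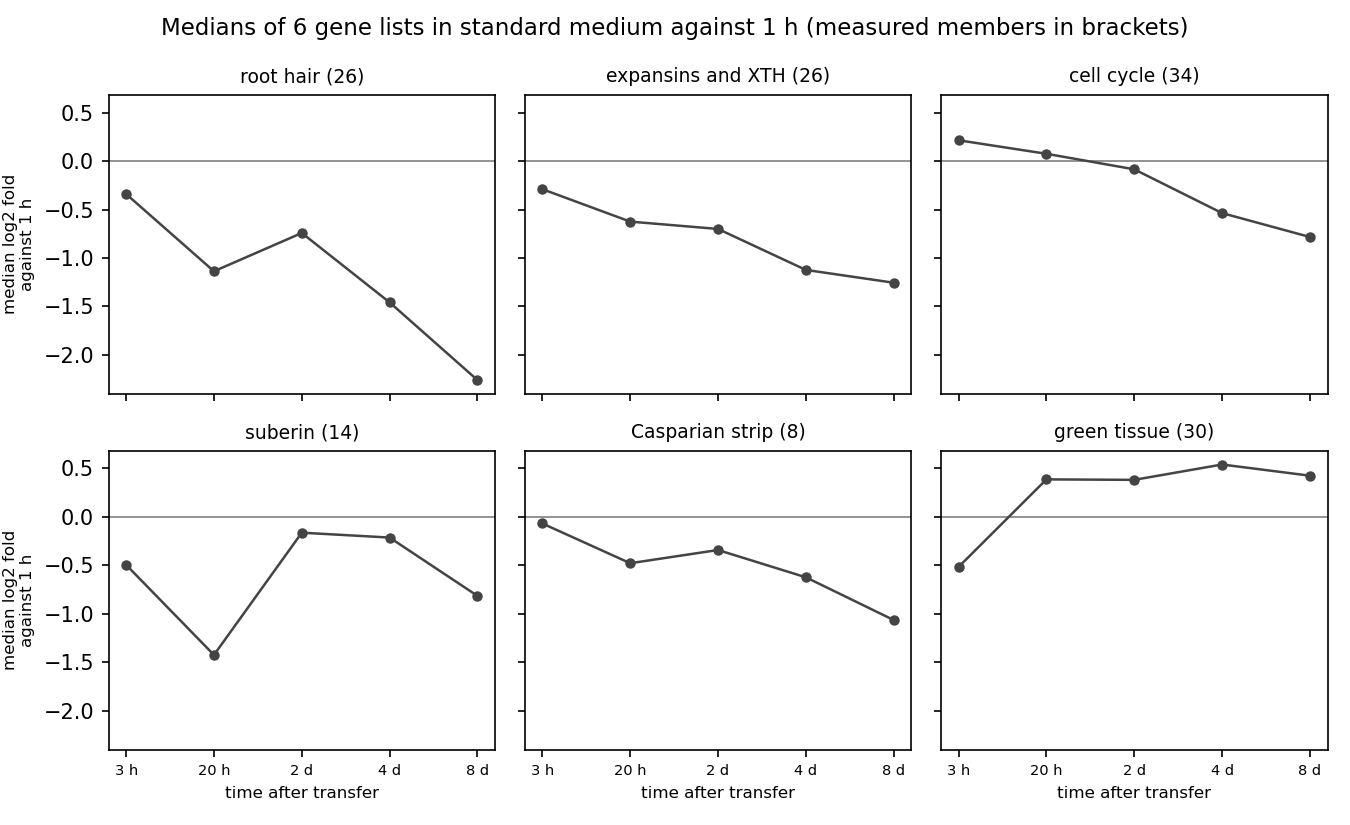
Median log2 fold of 6 gene lists in standard medium against 1 hour, 2 arrays per time. The root hair median reached -2.26 and the cell cycle median -0.78 at 8 days.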

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

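The tests of slides, of the standard roots and of list differences between times in this part were chosen only after the results were seen, the last adjusted over 510 tests (all lists and pairs of times). The F test over differences between times called 8354 genes whose salt effect was not equal at the 6 times.

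Root hair genes stood lower in salt at 1 hour (median -0.84) and higher at 20 hours (median 1.31), a difference of 2.15 (camera adjusted p = 3.88e-09, 0.507 with estimated correlation). Between these times the list moved by 1.15 in the salt roots (bootstrap interval 0.839 to 1.85) and by -1.14 in the standard roots. These times lay on different slides, so that a change of the standard roots alone could not be told apart. Salt effects were taken within slides holding both media, where a slide difference shared by both media cancels. The smallest difference over the 4 combinations of slides was 1.72. As such a slide difference cancels whatever the value, this does not test it. A slide difference acting on 1 medium could not be told apart, because these times shared no slide. At 2 days the list was lower (median -0.83, adjusted p = 0.0057, 0.758 with estimated correlation, 0.45 without standard replicate 2). The cause stays open.

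The median of the cell cycle list was -1.18 at 3 hours and -0.25 at 20 hours, a difference given no list test here. At 20 hours 0 of 34 passed in limma, although camera called the list (adjusted p = 0.0261, 0.761 with estimated correlation, 0.149 without salt replicate 1). The list moved by 0.821 in the salt roots (0.564 to 1.06 over its genes) and by -0.0954 in the standard roots, again on different slides. A change of the standard roots alone could therefore not be told apart. Over the slide combinations the smallest difference of within-slide salt effects was 0.878. A slide difference shared by both media cancels here whatever the value, and one acting on 1 medium could not be told apart. The list was lower at 2, 4 and 8 days too (medians -0.66, -0.57 and -0.75, adjusted p = 0.303, 0.421 and 0.303 with estimated correlation) and the cause stays open.

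Green tissue genes were higher in salt at 2, 4 and 8 days (medians 1.16, 1.09 and 1.47, adjusted p = 0.303, 0.303 and 0.276 with estimated correlation). Probes shared between LHCB1 and RBCS copies were argued against by the other members, whose lowest median was 1.07, and a single slide as the source by the lowest median on any slide, 0.922. Pieces of shoot could not be told apart from greening of the roots. The 12 shoot markers outside photosynthesis had medians of -0.164, 0.0265 and 0.293. Their upper bootstrap bounds, over markers and not arrays, were 0.188, 0.602 and 1.21, the last 2 more than 50% of the green medians. Of these markers CER1 rose at each time (1.39, 1.88 and 1.92) and ESM1, above background on 2 of 4 arrays, at 2 days (2.40), while LTP1, above background on all 4, stood at -0.0374, 0.463 and 0.0371 (adjusted p = 0.972, 0.538 and 0.971). Greening of salt-treated roots may account for the pattern, and so may shoot tissue at 4 and 8 days.

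Expansins and XTH differed by 1.32 between 20 hours and 1 hour (adjusted p = 0.000132, 0.187 with estimated correlation). The xylem and secondary wall list differed by 1.87 between 3 hours and 8 days (adjusted p = 1.61e-06, 0.442 with estimated correlation).

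Single genes changed sign between times in 54 named cases, given as the log2 fold at the higher and the lower time with the adjusted p of the F test. Both calls stayed without any 1 array for 21 of them. XTH33 was higher at 20 hours (2.75) and, dim in salt, at least 31.5-fold lower at 3 hours (2.79e-06). Higher at 20 hours and lower at 1 hour were NRT2.1 (3.73 and -4.60, 0.000109), ABCG2 (2.31 and -1.69, 4.45e-05), XTH18 (1.32 and -2.26, 0.000121) and MYB34 (1.81 and -1.71, 2.7e-06). The reverse was seen for AT5G56100 (3.35 and -4.08, 8.07e-06), TA25819_3702 (1.78 and -3.14, 2.29e-05) and TOC1 (0.91 and -0.79, 8.74e-05). Lower at 1 hour were also sks9, higher at 4 days (3.41 and -4.52, 3.1e-05), and PCO1 (2.63 and -2.09, 4.16e-05) and JAZ6 (1.18 and -1.43, 7.3e-05), higher at 2 days. From lower at 1 hour to higher at 3 hours went AT5G26220 (3.88 and -2.74, 0.000302), CYP86A4 (4.18 and -1.79, 9.89e-06), AT5G67430 (2.13 and -2.85, 0.000457) and FRK1 (2.07 and -2.15, 0.000544). From higher at 1 hour to lower at 3 hours went BT1 (2.64 and -2.32, 3.02e-05) and AT1G75960 (1.74 and -2.63, 7.5e-05). FAH1 (2.88 and -2.77, 0.000101), LHCB5 (1.73 and -1.57, 5.5e-05) and PSAK (1.72 and -0.95, 0.000105) were lower at 3 hours and higher at 8 days, and AT5G54300 was higher at 3 hours and lower at 20 hours (2.73 and -1.70, 4.16e-05).

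For the other 33 a call ended without 1 array, for 28 of them without more than 1 single array. The last value is the highest adjusted p, reached without the array named. The calls at both times ended for 6, with a highest adjusted p at the other time of 0.0919 for BST1, 0.122 for AT5G36270, 0.138 for GSTF8, 0.115 for HOL2, 0.0908 for ALDH11A3 and 0.0728 for AT5G50130. Without standard replicate 1 at 20 hours these were AT5G25260 (at least 1.54-fold higher at 20 hours, dim in standard medium, and at least 22.3-fold lower at 8 days, dim in salt, 7.16e-05, 0.283), XTH12 (2.86 at 20 hours and -3.22 at 1 hour, 0.00301, 0.135), AT5G36270 (3.01 at 20 hours and -3.05 at 3 hours, 0.00991, 0.169) and BST1 (1.39 at 20 hours and -1.47 at 1 hour, 0.0072, 0.126), and without standard replicate 2 AT3G63380 (0.88 at 20 hours and -3.93 at 8 days, 4.35e-06, 0.0605). Without salt replicate 1 at 20 hours it was AT5G62420 (2.32 at 20 hours and -3.47 at 1 hour, 0.000699, 0.0858), and without salt replicate 2 XTH17 (0.73 at 20 hours and -1.68 at 1 hour, 0.000444, 0.303) and SUR1 (0.80 at 20 hours and -1.07 at 3 hours, 0.000125, 0.0579). At 1 hour it was FAR4 without standard replicate 1 (3.19 at 20 hours and -1.14 at 1 hour, 2.48e-05, 0.0623), AT1G19530 without salt replicate 1 (2.60 at 1 hour and -2.87 at 20 hours, 0.00238, 0.0514) and ERF2 without salt replicate 2 (3.78 at 8 days and -1.25 at 1 hour, 2.67e-05, 0.208). Without standard replicate 2 at 1 hour these were ATCTH (1.88 at 1 hour and -3.92 at 3 hours, 0.000231, 0.241), SAUR9 (4.08 at 8 days and -1.62 at 1 hour, 5.49e-05, 0.0884, measured on 1 salt array alone at 1 hour, so that the call could not be fitted without salt replicate 2), IAA3 (1.66 at 1 hour and -2.43 at 8 days, 0.00302, 0.16) and RHD2 (0.90 at 20 hours and -0.75 at 1 hour, 0.00586, 0.0643). At 3 hours it was CAT3 without salt replicate 1 (2.06 at 2 days and -1.01 at 3 hours, 0.00163, 0.171), TSA1 without standard replicate 2 (5.5 at 4 days and -1.47 at 3 hours, 1.76e-05, 0.204), and VSP2 (3.54 at 2 days and -1.41 at 3 hours, 0.000393, 0.215) and GSTF8 (0.47 at 3 hours and -0.66 at 4 days, 0.0114, 0.16) without salt replicate 2. Without salt replicate 2 at 2 days it was AT1G49450 (5.16 at 3 hours and -2.12 at 2 days, 2.3e-05, 0.121), and without standard replicate 2 HOL2 (2.33 at 2 days and -2.26 at 20 hours, 0.0116, 0.171), ALDH11A3 (2.01 at 2 days and -2.33 at 3 hours, 0.00281, 0.307) and GID1A (0.72 at 2 days and -1.19 at 3 hours, 0.000142, 0.119). Without salt replicate 2 at 4 days these were AT5G50130 (1.53 at 4 days and, dim in salt, at least 2.26-fold lower at 1 hour, 0.00252, 0.219), KCS20 (2.03 at 3 hours and -0.81 at 4 days, 0.000102, 0.126), CYCD3;1 (1.02 at 4 days and -1.38 at 1 hour, 0.000105, 0.0753) and PYL9 (1.14 at 1 hour and -0.74 at 4 days, 0.000877, 0.128). At 4 days it was also AT2G22510 without standard replicate 1 (3.1 at 20 hours and -1.42 at 4 days, 0.000484, 0.207) and CYP79B2 without standard replicate 2 (1.84 at 4 days and -2.50 at 3 hours, 0.000149, 0.0558). At 8 days CYP71A12 (at least 12.4-fold higher at 2 days, dim in standard medium, and -3.34 at 8 days, 0.000824, 0.103), WRKY33 (1.91 at 1 hour and -0.56 at 8 days, 3.1e-05, 0.185) and ZAT12 (1.40 at 1 hour and -0.96 at 8 days, 0.00644, 0.399) lost a call without standard replicate 1, and PR5 (3.03 at 20 hours and -1.19 at 8 days, 3.87e-05, 0.101) without standard replicate 2.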

How the results depend on the processing

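The alternatives chosen after seeing the data were leaving out population outlier spots, leaving out the 8-day time, normexp without spots of bright local background, and the list tests with the slide as a block or with each array left out. All salt counts stayed within 1.5 times of those reported with quantile or median scaling, no filter, the stricter filter, the mean of a gene's probes, the deposited log2 values, the trended robust variance, the fixed slide and the replicate block, and without population outlier spots or the 8-day time. The cause was not tested where none is named.

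Planned normexp gave 1569, 2541, 1107, 233, 187 and 477 genes at the 6 times, 4880 for the mean, 3821 at any time and 1152 differing between times. Its steps gave 255, 276 and 81 genes, and from 4 to 8 days 0 (limma, 368 at unadjusted p under 0.05), and its standard course 1, 66, 3, 442 and 1961. It reversed AT3G11385 (0.16), DR355474 (0.82), NCED3 (0.99), PYL2 (0.60), LBD18 (1.105), LBD29 (0.999) and IAA19 (0.47) at 4 days, CKX3 (0.45) and CRU3 (1.58) at 3 hours, and LEA4-1 (-1.48), JAZ3 (-0.0562) and CKX5 (-0.026) at 20 hours. On salt replicate 1 of 3 hours, standard replicate 1 of 20 hours and salt replicate 2 of 4 days its fitted background was -681, -1540 and -1370, against -20.1 to -0.749 elsewhere. Without 21 spots of bright local background the counts moved by over 1.5 times only to 1 gene from 2 to 4 days and 10 from 4 to 8 days, with SOS1 at 0.000781 at 20 hours.

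With quantile scaling 1 and 5 genes passed from 2 to 4 and from 4 to 8 days. Without the filter 718 genes passed from 20 hours to 2 days and 79 in standard medium at 3 hours, with 34176 genes tested. The replicate block changed the steps from 20 hours to 2 days (2125), 2 to 4 days (1) and 4 to 8 days (0, limma, 1744 at unadjusted p under 0.05), and of the named genes 8 gained and 10 lost a call. The fixed slide block gave 4578 from 3 to 20 hours, 2218 from 20 hours to 2 days, 2 from 2 to 4 days and 254 in standard medium at 3 hours. The random slide block gave 5771 at 2 days, 4762, 2686 and 5 for the steps to 20 hours, 2 days and 8 days, and 414 in standard medium at 3 hours. The standard course could not be fitted with the replicate block, nor beyond 3 hours with the fixed slide block.

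With a 2-fold minimum 3209, 4827, 2788, 1653, 1904 and 2214 genes remained at the 6 times, 2217 for the mean, 2482 from 1 to 3 hours, and 718, 640, 2223 and 4016 in standard medium from 20 hours on. At a threshold of 0.01 there were 4082 at 1 hour, 3282 at 20 hours, 1627, 2008 and 2722 at 2, 4 and 8 days, 4829 differing between times, 1812, 1240, 326 and 1 for the steps to 3 hours, 20 hours, 2 days and 8 days, and 27, 342, 256, 2942 and 6132 in the standard course. With only the 4 arrays compared there were 2037 at 1 hour, 1015 at 2 days and 0 at 8 days (limma, 4176 at unadjusted p under 0.05), and in the standard course 0, 0, 0 and 0 (1488, 4092, 3591 and 7296) and 830 at 8 days, while at 3 hours, 20 hours and 4 days there were 6376, 4614 and 3653. With the replicate and the fixed slide block camera also called cell cycle at 1 hour (adjusted p = 0.0318 and 0.0239) and root hair at 3 hours (0.027 and 0.0383), and no longer cytokinin at 20 hours (0.0576 and 0.0595) and auxin at 8 days (0.0616 and 0.0541). The replicate block alone gained nitrogen at 20 hours (0.0487) and iron deficiency at 4 days (0.0405), and the slide block lost iron deficiency at 8 days (0.0735). Quantile scaling gained indole glucosinolate and camalexin at 1 hour (0.0477) and lost green tissue at 1 hour (0.0681) and aquaporins (0.0616) and circadian clock (0.0622) at 3 hours. With an estimated correlation camera called 0 lists at each time, with 6, 7, 9, 7, 6 and 2 at unadjusted p under 0.05.

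Without 1 array, the lone array being assumed to vary like the other groups, counts ranged from 3322 to 6721 at 20 hours, 1310 to 4637 at 2 days and 1951 to 5185 at 4 days. For the steps they ranged from 2513 to 4601, 1576 to 3843, 372 to 2006, 0 to 3 and 0 to 431 (at 0, limma gave 332 to 767 at unadjusted p under 0.05), and for the standard course from 24 to 234, 179 to 2281, 174 to 1852, 2093 to 7750 and 5326 to 11045. Key genes that passed no test there changed sign, namely RAB18 at 1 hour (-0.28 to 0.80), 20 hours (-0.52 to 0.65) and 8 days (-0.48 to 1.33), HKT1 at 1 hour (-1.26 to 0.35), SOS1 at 20 hours (-0.29 to 0.0797), NCED3 at 2 days (-0.50 to 0.22) and 4 days (-0.29 to 0.0501), DREB2A at 2 days (-0.0625 to 0.27) and 8 days (-1.52 to 0.0773), and NHX1 at 8 days (-0.27 to 0.0141). Signal over background limits folds of dim genes to bounds.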

Other observations

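The 8 lists that camera called at no salt time still held genes that responded at 3 hours. Of ion transport genes 6 of 20 rose and 4 fell (6 and 5 over the list alone), with the exchanger gene CAX3 (2.59 ± 0.20, adjusted p = 2.71e-07), the potassium channel gene GORK (2.92 ± 0.29, adjusted p = 3.32e-06) and the vacuolar exchanger gene NHX2 (1.21 ± 0.14, adjusted p = 9.93e-06) higher and KUP8 lower (-2.78 ± 0.27, adjusted p = 2.98e-06). The list median was 0.00895 (adjusted p = 0.492, 0.609 with estimated correlation). Ethylene genes rose in 5 of 12 cases and fell in 1 (5 and 1 over the list alone), with the synthesis genes ACS6 (4.09 ± 0.30, adjusted p = 2.17e-07) and ACS2 (3.02 ± 0.29, adjusted p = 2.39e-06) higher and ACO1 lower (-1.99 ± 0.30, adjusted p = 0.000123). Their median was -0.0756 (adjusted p = 0.21, 0.544 with estimated correlation). Gibberellin genes fell in 8 of 20 cases and rose in 3 (8 and 3 over the list alone), with the repressor gene RGA (-0.89 ± 0.12, adjusted p = 4.86e-05) and the receptor gene GID1A (-1.19 ± 0.17, adjusted p = 6.83e-05) lower and GA2OX6, of gibberellin breakdown, higher (3.00 ± 0.23, adjusted p = 3.3e-07). The gibberellin median was -0.32 (adjusted p = 0.743, 0.883 with estimated correlation). Of the brassinosteroid genes 5 of 14 fell and 2 rose (5 and 3 over the list alone), the synthesis genes BR6OX1 (-2.08 ± 0.24, adjusted p = 1.21e-05) and DET2 (-1.02 ± 0.13, adjusted p = 3.18e-05) among the former. This list had a median of -0.20 (adjusted p = 0.492, 0.654 with estimated correlation).

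Among 6 phosphate starvation genes PAP17 rose (3.83 ± 0.20, adjusted p = 1.27e-08) and PHT1;1, of phosphate uptake, fell (-2.28 ± 0.37, adjusted p = 0.000224), with a median of -0.46 (adjusted p = 0.858, 0.928 with estimated correlation). In the salicylate and pathogen response list PR5 (1.84 ± 0.32, adjusted p = 0.000371) and FRK1 (2.07 ± 0.39, adjusted p = 0.000716) rose and PAD4 fell (-0.71 ± 0.10, adjusted p = 8.92e-05), 3 of 4 genes, with a median of 0.76 (adjusted p = 0.58, 0.758 with estimated correlation). Of 8 root tip and stem cell niche genes SHR fell (-1.18 ± 0.14, adjusted p = 1.96e-05), and BRN2 (0.99 ± 0.27, adjusted p = 0.00932) and BRN1 (1.06 ± 0.32, adjusted p = 0.0182) rose, both only while salt replicate 1 was included (adjusted p = 0.05 and 0.128 without it, and 0.12 for BRN1 without standard replicate 2). This list had a median of -0.0143 (adjusted p = 0.969, 0.986 with estimated correlation). Of 5 seed storage genes the oleosin gene OLEO2, dim in standard medium, was at least 1.82-fold higher, and CRU3, dim in salt, at least 1.44-fold lower (adjusted p = 0.0491, 0.32 without salt replicate 1), 1 gene in each direction (the same over the list alone). The seed storage median was 0.0639, or -0.23 with dim members at their bound or left out (adjusted p = 0.851, 0.906 with estimated correlation).

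Chance was tested for the mean salt effect by exchanging the medium labels within times. Of 100 such splits only 1, the real one, gave as many as 13387 genes, the highest other giving 7341. This argues against chance among arrays but cannot test cultures or slide position. The split by replicate number gave 926.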
